A study of Mus musculus with 15 samples.

How the data were processed

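RNA of PDGFRa-positive fibroblasts, sorted by flow cytometry from mouse kidney, was amplified, labelled with biotin and measured on 15 arrays. The deposited values are log2 intensities of 45141 probe sets per array, made by the authors with RMA per the submitters' processing notes, which also name affy and limma without versions or roles. The values ran from 2.43 to 13.1, no 2 arrays were identical, and they were used without further normalization. No background signal or detection call was used here, so folds against dim values are compressed. The samples carry running numbers that are not shared between groups, so nothing pairs them. Nothing used here says whether the 3 arrays of a group came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

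Probe sets were matched to genes through the platform annotation, and symbols were looked up by Entrez identifier in the mouse gene table. Of the probe sets 28898 named 1 gene, 551 named several and 15692 were not named in the annotation used here. The lookup matched 28689 probe sets and changed 0 symbols. Probe sets of 1 gene gave 17097 genes, of which 7180 had more than 1 probe set, and the probe set with the highest mean stood for its gene. Another probe set was called in the opposite direction for 27, 11, 5 and 15 of the genes called at folic acid day 3, day 7, day 14 and in UUO against uninjured kidney. A gene was tested if it lay above the 40th percentile of its array in at least 3 arrays, which kept 13523 genes and left out 3574 as dim. No coordinates were used.

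One mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with 10 residual degrees of freedom). Each injury group was compared with uninjured kidney, UUO with folic acid day 14, and the folic acid days with one another, by limma's 2-sided moderated test. Adjustment was by Benjamini-Hochberg within each comparison over the genes tested, and a gene was called at an adjusted p under 0.05. An F test asked for any difference among the 5 groups. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Calls shared by folic acid day 14 and UUO were compared with 100 simulations of unchanged groups against the same controls. Plots were drawn with matplotlib 3.10.9.

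The lists covered fibrillar and associated collagens, basement membrane, matrix glycoproteins, collagen processing, matrix proteases and inhibitors, contractile genes, TGF-beta, Wnt, hedgehog, retinoid and cell cycle genes. Others covered chemokines and cytokines, complement, interferon, hypoxia, the unfolded protein response, oxidative stress, fatty acid oxidation, immediate early and dissociation stress genes and resident kidney fibroblasts. They also covered markers of pericytes, proximal tubule, distal nephron, injured or simple epithelium, endothelium, podocytes, macrophages and dendritic cells, lymphocytes, neutrophils and erythroid cells. The comparisons, these 30 gene lists and the rule for named genes were fixed before the data were examined. The lists held 521 entries and 518 genes, of which 461 were measured and 422 tested. The other listed genes were not analysed here, and 29 lists had the 5 tested genes required, which the erythroid list did not. For each main comparison the rule named the 6 highest and 6 lowest log2 changes among called genes whose groups did not overlap, leaving out provisional symbols. For comparisons of folic acid days it named 3 and 3. It added Pdgfra, Acta2, Col1a1, Col3a1, Fn1, Postn, Tnc, Timp1, Mki67 and Ccl2, and up to 4 called members with the smallest p of each list described, or 2 members if none was called.

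The fit was tested on simulated data with 100 genes changed by log2 1 and 100 by log2 2 in each comparison. The shares recovered at log2 1 and log2 2 were 39% and 81% for folic acid day 3 against uninjured kidney, 43% and 84% for day 7, 47% and 87% for day 14 and 49% and 83% for UUO. They were 42% and 83% for UUO against folic acid day 14, 39% and 86% for day 7 against day 3, 51% and 85% for day 14 against day 7, and 41% and 73% for day 14 against day 3. False calls numbered 8, 11, 9, 8, 5, 8, 3 and 3 in that order. Every comparison was simulated from the same gene means and the same pooled SD per gene, with noise independent between genes. Differences between these shares therefore do not rank the comparisons. The real groups differ in spread (median SD 0.186 in uninjured kidney and 0.298 at folic acid day 14), and their genes are correlated, which the simulation left out.

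The results were also computed with quantile normalization, median centring, trend and robust settings, array weights, only the 6 arrays compared, no filter on dim genes, a filter at the 60th percentile and the mean of probe sets. Further settings were leaving out each array in turn, a fold of at least 2, a threshold of 0.01, camera with an estimated correlation, and fry, which tests whether a list moves one way on balance. Another 3 settings were chosen after seeing the data: the mean of the proximal tubule list as a covariate, the mean of the macrophage list as a covariate, and leaving out the 3 injured arrays with the highest proximal tubule mean (folic acid day 7 array 1 and day 14 arrays 1 and 2). Leaving these out leaves 1 folic acid day 14 array, so counts of that setting for comparisons with day 14 are not given. Other splits of the same arrays were also counted.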

Results

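RNA was measured on 15 oligonucleotide arrays of PDGFRa-positive fibroblasts, sorted by flow cytometry from kidneys of adult C57BL/6 mice. PDGFRa is a growth factor receptor on the surface of kidney fibroblasts, the interstitial cells that make scar matrix. The arrays fell into 5 groups of 3. They came from uninjured kidney, from kidney at day 3, day 7 or day 14 after folic acid, and from kidney at day 14 of unilateral ureteral obstruction (UUO). Folic acid injures tubule epithelium and starts acute kidney injury, and a blocked ureter produces progressive fibrosis. Levels are mean log2 values ± SD with n = 3 arrays per group. Changes are log2 differences with their standard error (SE), and all adjusted p-values come from limma. The array medians lay between 4.93 and 5.06 on the log2 scale. Correlations across genes, which are not independent replicates, ran from 0.938 to 0.976 between uninjured arrays, from 0.863 to 0.902 between day 7 arrays and from 0.889 to 0.901 between day 14 folic acid arrays. Day 7 arrays 1, 2 and 3 each correlated more closely with an array of another group (0.906, 0.910 and 0.925) than day 7 arrays did with one another. So did folic acid day 14 arrays 1 and 3 (0.906 and 0.919). For day 14 array 2 the nearest array of another group was uninjured array 2 (0.900). The number of arrays limits the precision of every value.

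Of 13523 genes tested, 2070 differed among the 5 groups in an F test at an adjusted p of 0.05. Pdgfra itself, the gene behind the sort, had a mean of 6.01 ± 0.38 in uninjured kidney, 6.69 ± 0.55 at folic acid day 3, 5.50 ± 1.00 at day 7, 5.28 ± 1.20 at day 14 and 5.99 ± 0.48 in UUO. Its log2 change against uninjured kidney ranged from -0.72 (SE 0.59, adjusted p = 0.540) at day 14 to 0.68 (SE 0.59, adjusted p = 0.465) at day 3, so no difference passed the test. Except at day 3, its means lay between the array medians (4.93 to 5.06) and the array upper quartiles (6.18 to 6.27). With errors of this size the lack of a call does not show equal levels. Transcripts of tubule cells, which the sort was meant to exclude, were bright in some arrays. The mean of 13 proximal tubule markers was 8.82 ± 0.64 in uninjured kidney, 6.80 ± 0.05 at folic acid day 3, 7.03 ± 1.33 at day 7, 8.48 ± 1.16 at day 14 and 5.79 ± 0.27 in UUO. Folic acid day 7 array 1, at 8.42, and day 14 arrays 1 and 2, at 9.27 and 9.02, lay closest to the uninjured arrays. Every UUO and folic acid day 3 array lay at 6.86 or below, and every uninjured and folic acid day 14 array at 7.14 or above. Comparisons across this gap with that mean as a covariate are therefore extrapolated. The F test count was 1107 without uninjured array 2, 1282 without uninjured array 3, 3291 with array weights and 973 with the proximal tubule mean as a covariate.

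**Figure D1:**
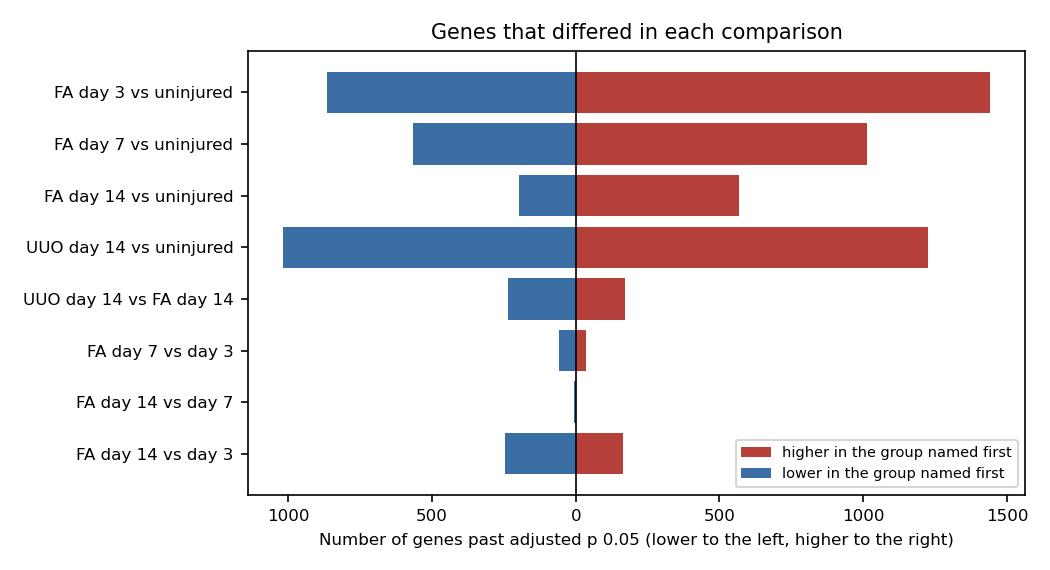
Number of genes past an adjusted p of 0.05 in each of 8 comparisons; bars to the right count genes higher, and bars to the left genes lower, in the group named first (FA, folic acid). The longest bars belong to folic acid day 3 against uninjured kidney, with 1440 genes higher, and UUO against uninjured kidney, with 1017 genes lower.

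The comparison of folic acid day 3 with uninjured kidney asked how the sorted cells differed early after acute injury. The fibrillar collagen gene Col3a1 rose 87.2-fold (log2 6.45, SE 0.42, adjusted p = 2.58e-06). Col6a1 rose 70.3-fold (log2 6.13, SE 0.26, adjusted p = 6.16e-08) and Cdh11, a cadherin of mesenchymal cells, rose 64.7-fold (log2 6.02, SE 0.28). Clca3a1 and Clca3a2, closely related genes that these probe sets were not tested to separate, rose 130-fold (log2 7.03, SE 0.47) and 102-fold (log2 6.67, SE 0.68). The organic anion transporter Slco2b1 rose 72.3-fold. Acta2, the smooth muscle actin that marks myofibroblasts, went from 8.29 ± 0.12 to 12.08 ± 0.10. Col1a1 went from 6.81 ± 0.08 to 12.05 ± 0.15, the protease inhibitor Timp1 from 5.14 ± 0.03 to 10.20 ± 0.18, fibronectin (Fn1) from 6.02 ± 0.28 to 9.94 ± 0.05 and periostin (Postn) from 4.96 ± 0.20 to 9.56 ± 0.20. The lowest changes were those of the conjugating enzyme Ugt3a2 (log2 -5.25, SE 1.16), the organic anion transporter Slc22a8 (log2 -5.23, SE 1.06) and Dnase1 (log2 -4.90, SE 1.07). The other 3 were the peroxisomal oxidase Hao2 (log2 -4.90, SE 1.09), the thick limb salt transporter Slc12a1 (log2 -4.75, SE 0.66) and Cyp2d26 (log2 -4.61, SE 1.19).

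Among the gene lists, 14 of 16 fibrillar and associated collagens rose at day 3 and none fell, with 14 higher adjusted over the list alone (median log2 4.13, camera adjusted p = 3.3e-18, adjusted p = 0.055 with an estimated correlation). Of 23 matrix glycoproteins 17 rose, 18 adjusted over the list alone, including Ogn (log2 4.68), Fbln5 (log2 5.13) and Mgp (log2 3.66); adjusted p = 0.055 with an estimated correlation. Of 14 collagen processing genes 10 rose, including the crosslinking oxidases Lox (log2 4.36) and Loxl2 (log2 4.59) and the collagen chaperone Serpinh1 (log2 2.69). Adjusted over the list alone 12 were higher, and the adjusted p was 0.055 with an estimated correlation. Contractile genes rose in 8 of 16 cases, with Acta2, Tpm2 (log2 2.63), Tpm4 (log2 3.22) and Vim (log2 1.68) among them (9 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). In the cell cycle list, 10 of 29 genes rose and none fell, 14 adjusted over the list alone, with the nucleotide reductase subunit Rrm2 at log2 2.95, Birc5 at log2 1.97 and the cyclin Ccnb2 at log2 1.65. This shift also held with an estimated correlation (camera adjusted p = 2.9e-05, adjusted p = 0.032 with an estimated correlation). The proliferation marker Mki67 itself was 2.32 higher (SE 0.75) and did not pass (adjusted p = 0.051). Retinoid genes split, as the retinoic acid synthases Aldh1a2 (log2 5.65) and Aldh1a1 (log2 3.59) rose and Dhrs3 fell. Over all genes and adjusted over the list alone, 4 of 11 were higher and 1 was lower, and the list did not shift (camera adjusted p = 0.16). The call of Dhrs3 ended when any 1 of 3 arrays was left out and with the proximal tubule covariate, where its change was log2 -0.72 (adjusted p = 0.309).

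Tubule markers moved the other way from matrix genes at day 3. In the distal nephron and collecting duct list 10 of 15 fell and none rose, 13 adjusted over the list alone, with Slc12a3, the distal tubule salt transporter, at log2 -3.81 and Kcnj1 at log2 -3.15 (adjusted p = 0.10 with an estimated correlation). Of 13 proximal tubule markers 5 fell, also 5 adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). Of 7 podocyte markers 5 fell, including Podxl (log2 -2.61) and Nphs1 (log2 -1.36), and Tcf21, which is also a fibroblast gene, rose (log2 4.52). Adjusted over the list alone 6 were lower and 1 higher (adjusted p = 0.055 with an estimated correlation). In the macrophage and dendritic cell list 4 of 21 rose (5 adjusted over the list alone), among them Lyz2 (log2 2.99), and the list did not shift (camera adjusted p = 0.19). In all 2304 genes passed, 1440 higher and 864 lower, a 62.5% share higher that became 51.0% after quantile normalization. The count was 1463 and 1503 without uninjured arrays 2 and 3, 1114 at the stricter threshold of 0.01, 1050 with the proximal tubule mean as a covariate and 1514 with the macrophage mean. The call of Cyp2d26 ended when any 1 of 3 arrays was left out and that of Tnc (log2 1.89) when any 1 of 8 was. With the proximal tubule covariate Ugt3a2 (log2 -2.13), Hao2 (log2 -1.66), Cyp2d26 (log2 -0.96) and Tnc (log2 1.04) no longer passed. Slc22a8 (log2 -1.87) and Dnase1 (log2 -1.56) still passed with it but shrank. The proximal tubule markers Cubn, Miox and Slc5a12 lost their calls without uninjured array 3, and also with this covariate. They and Slc22a8 are members of the list behind the covariate, so their shrinking with it is built in.

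At folic acid day 7 the same question was put one step later in the course. Cdh11 rose 94.4-fold (log2 6.56, SE 0.28, adjusted p = 5.81e-08). Col3a1 rose 74.9-fold (log2 6.23, SE 0.42) and the scavenger receptor gene Colec12 rose 56.8-fold (log2 5.83, SE 0.30). Lyz2, the lysozyme of macrophages, went from 4.34 ± 1.40 to 10.40 ± 0.27 (log2 6.05, SE 0.51, adjusted p = 1.73e-05). Clca3a1 rose by log2 6.03 (SE 0.47) and Lgi2 by log2 5.46 (SE 0.44). Col1a1 stood at 11.83 ± 0.17, Timp1 at 10.15 ± 0.54, Fn1 at 10.20 ± 0.45 and Acta2 at 11.05 ± 0.11, each above uninjured kidney, as was the matricellular gene Tnc (log2 2.99, SE 0.57). Postn was 2.09 higher (SE 0.85, adjusted p = 0.135). The lowest changes were those of Hao2 (log2 -3.89, SE 1.09), Dnase1 (log2 -3.70, SE 1.07) and the acyl-CoA synthetase Acsm2 (log2 -3.51, SE 0.83). Next came Zcchc3 (log2 -3.38, SE 0.67), the glucose-releasing phosphatase G6pc (log2 -3.33, SE 0.93) and Egf (log2 -3.30, SE 0.95), a growth factor made by distal tubules.

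Collagens rose in 14 of 16 cases at day 7, also 14 adjusted over the list alone (median log2 3.40, adjusted p = 0.058 with an estimated correlation), with Col6a1 at log2 5.29 and Col15a1 at log2 5.30. Of 23 matrix glycoproteins 16 rose, 19 adjusted over the list alone, led by Ltbp2 (log2 4.80), Mfap4 (log2 4.87) and Mgp (log2 3.98); adjusted p = 0.058 with an estimated correlation. Of 18 matrix proteases and inhibitors 13 rose, including Mmp2 (log2 2.34), Mmp14 (log2 2.29) and Mmp19 (log2 2.03), and 2 fell (14 and 4 adjusted over the list alone; adjusted p = 0.074 with an estimated correlation). Wnt pathway genes rose in 9 of 15 cases, including the pathway inhibitor Nkd2 (log2 3.84), the secreted antagonist Frzb (log2 3.96) and the target gene Ccn4 (log2 2.98), while 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Complement genes rose in 4 of 8 cases, with the inhibitor Serping1 at log2 3.33. Adjusted over the list alone 6 were higher, and the adjusted p was 0.13 with an estimated correlation. Of these calls, those of C1s1 and C1ra ended when any 1 of 4 and 6 arrays, in that order, was left out. Neither passed with the proximal tubule covariate (adjusted p = 0.340 and 0.263). None of 29 cell cycle genes passed, over all genes or adjusted over the list alone, with Rrm2 at log2 1.10 (adjusted p = 0.071); the list had a median of 0.29 (camera adjusted p = 0.083).

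Macrophage genes rose at day 7 alongside the matrix genes. Of 21 macrophage and dendritic cell markers 14 rose and none fell, 16 adjusted over the list alone (median log2 2.76, camera adjusted p = 5.4e-16, adjusted p = 0.074 with an estimated correlation), including the antigen presentation genes H2-Aa (log2 4.14) and Cd74 (log2 3.49) and the lysosomal protease Ctss (log2 5.18). The distal nephron list fell in 6 of 15 members, 9 adjusted over the list alone (adjusted p = 0.13 with an estimated correlation), and the proximal tubule list in 2 of 13, 8 adjusted over the list alone (adjusted p = 0.30 with an estimated correlation). In all 1580 genes passed, 1014 higher and 566 lower, a 64.2% share higher that became 51.6% after quantile normalization. The count was 904 without day 7 array 2, 880 and 888 without uninjured arrays 2 and 3, 619 at the threshold of 0.01, 744 with the proximal tubule covariate and 9 with the macrophage mean as a covariate. The calls of Hao2, G6pc, Dnase1, Egf and Acsm2 ended when any 1 of 5, 5, 11, 10 and 2 arrays, in that order, was left out. With the proximal tubule covariate they stood at log2 -1.02, -0.85, -0.75, -1.26 and -1.38 and Tnc at log2 2.23, and none of these 6 passed.

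At folic acid day 14, the latest time of the acute model, the largest rise was that of Lyz2 (72.5-fold, log2 6.18, SE 0.51, adjusted p = 2.39e-05). Col3a1 (52.8-fold, log2 5.72, SE 0.42) and Cdh11 (47.1-fold, log2 5.56, SE 0.28) followed. Next were Ctss (36.9-fold, log2 5.20, SE 0.51), Colec12 (28.8-fold, log2 4.85, SE 0.30) and the myeloid adaptor Tyrobp (27.3-fold, log2 4.77, SE 0.55). Col1a1 stood at 11.17 ± 0.51 and Acta2 at 10.71 ± 0.60, above the uninjured 6.81 ± 0.08 and 8.29 ± 0.12. Timp1 and Fn1 rose by log2 4.06 (SE 0.38) and log2 3.61 (SE 0.33). Postn (log2 1.68, adjusted p = 0.293) and Tnc (log2 2.02, adjusted p = 0.0617) did not pass. The lowest changes were those of Zcchc3 (log2 -2.80, SE 0.67), the growth factor Fgf9 (log2 -2.80, SE 0.37) and the Ras pathway scaffold Shoc2 (log2 -2.24, SE 0.45). Klhdc7a (log2 -2.14, SE 0.36), Scyl2 (log2 -1.82, SE 0.27) and the sorting receptor Sorl1 (log2 -1.80, SE 0.43) followed.

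Collagens rose in 11 of 16 cases at day 14, 14 adjusted over the list alone (median log2 2.26, adjusted p = 0.074 with an estimated correlation). Matrix glycoproteins rose in 14 of 23 cases, with 15 higher and 1 lower adjusted over the list alone, including Ltbp2 at log2 3.98, Mgp at log2 3.57 and Mfap4 at log2 3.66 (adjusted p = 0.074 with an estimated correlation). Only Acta2 and Vim (log2 1.13) rose among 16 contractile genes, 5 adjusted over the list alone (adjusted p = 0.39 with an estimated correlation). Chemokine and cytokine genes rose in 5 of 20 cases, including the alarmin Il33 (log2 3.79), Cxcl16 (log2 2.44) and Cxcl14 (log2 3.64). Adjusted over the list alone 9 were higher and 1 lower, and the adjusted p was 0.23 with an estimated correlation. Immediate early and dissociation stress genes rose in 4 of 18 cases, with Fos at log2 3.17 and Egr2 at log2 2.33. Adjusted over the list alone 6 were higher, and the adjusted p was 0.23 with an estimated correlation. The calls of Egr1 and Hspa1b from this list ended when any 1 of 11 and 5 arrays, in that order, was left out. Whether injury or cell preparation raised these genes was not tested. Macrophage markers rose in 13 of 21 cases, 18 adjusted over the list alone, with H2-Aa at log2 4.41, Cd74 at log2 3.97 and H2-Ab1 at log2 4.05 (median log2 2.02, adjusted p = 0.074 with an estimated correlation). No member of the proximal tubule or distal nephron lists passed, over all genes or adjusted over the list alone, with medians of -0.41 and -0.22 (camera adjusted p = 0.45 for each). In all 767 genes passed, 568 higher and 199 lower, a 74.1% share higher that became 59.4% after quantile normalization. The count was 481 and 440 without day 14 arrays 1 and 3, 460, 350 and 412 without uninjured arrays 1, 2 and 3, 263 at the threshold of 0.01, 397 from only the 6 arrays compared and 2 with the macrophage covariate. The calls of Zcchc3, Sorl1 and Vim ended when any 1 of 5, 4 and 3 arrays was left out.

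The UUO arrays were compared with uninjured kidney to describe the chronic model. Cdh11 rose 122-fold (log2 6.93, SE 0.28, adjusted p = 3.34e-08) and Col3a1 rose by log2 6.66 (SE 0.42). Lgi2 and Colec12 rose 71.2-fold each (log2 6.15, SE 0.44 and 0.30), the microfibril gene Mfap4 rose 70.6-fold (log2 6.14, SE 0.42) and Col6a1 rose 57.9-fold (log2 5.85, SE 0.26). Col1a1 reached 12.23 ± 0.23, Acta2 12.02 ± 0.11, Fn1 10.74 ± 0.42, Tnc 10.34 ± 0.10, Timp1 9.47 ± 0.28 and Postn 9.21 ± 1.71, each higher than in uninjured kidney. The lowest changes were those of Ugt3a2 at log2 -5.98 (SE 1.16), the fatty acid transporter Slc27a2 at log2 -5.54 (SE 0.90), Cltrn at log2 -5.43 (SE 0.93) and Acsm2 at log2 -5.42 (SE 0.83). Cyp2j5 fell by 5.19 on the log2 scale (SE 0.91) and Cyp4a10 by 5.15 (SE 0.93).

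All 16 collagens rose in UUO, also adjusted over the list alone (median log2 3.79, camera adjusted p = 7.5e-23, adjusted p = 0.034 with an estimated correlation). Of 23 matrix glycoproteins 21 rose, 22 adjusted over the list alone, including Thbs2 (log2 4.30) and Mgp (log2 3.90). Of 14 collagen processing genes 11 rose, 13 adjusted over the list alone, including Loxl1 (log2 4.91) and the prolyl hydroxylase P4ha3 (log2 3.47). Both shifts held with an estimated correlation (adjusted p = 0.034 with an estimated correlation for each). Contractile genes rose in 10 of 16 cases, 11 adjusted over the list alone (adjusted p = 0.089 with an estimated correlation). TGF-beta pathway genes rose in 8 of 17 cases, also 8 adjusted over the list alone, among them the activin subunit Inhba (log2 2.81), Tgfbi (log2 3.79) and Skil (log2 2.34); adjusted p = 0.071 with an estimated correlation. Wnt genes rose in 9 of 15 cases and fell in 2, with 11 and 2 adjusted over the list alone, led by Frzb (log2 4.75) and Wnt5a (log2 3.70); adjusted p = 0.092 with an estimated correlation. Of 14 fatty acid oxidation genes 6 fell, including Hadhb (log2 -1.45) and Acadvl (log2 -1.17), and Pdk4 rose (8 lower and 2 higher adjusted over the list alone; adjusted p = 0.29 with an estimated correlation). The median of this list was -0.96, and 0.41 with the proximal tubule covariate. Rrm2 rose (log2 2.02) and Cenpf fell (log2 -0.62) among 29 cell cycle genes. Adjusted over the list alone 1 was higher and 0 were lower, and the list did not shift (camera adjusted p = 0.14).

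Tubule markers were lower in UUO than in uninjured kidney: 14 of 15 distal nephron genes fell, 14 adjusted over the list alone (median log2 -2.11, adjusted p = 0.071 with an estimated correlation), and 10 of 13 proximal tubule genes fell, 11 adjusted over the list alone (median log2 -3.32, adjusted p = 0.22 with an estimated correlation). Slc12a3 changed by log2 -4.74 and Calb1 by log2 -4.45. Of 21 macrophage markers 3 rose (H2-Aa, log2 2.63, Lyz2, log2 3.26, and Cd74, log2 1.13) and Mrc1 fell (log2 -2.30), with 4 higher and 1 lower adjusted over the list alone (median log2 0.34, -0.24 with the proximal tubule covariate, adjusted p = 0.48 with an estimated correlation). In all 2244 genes passed, 1227 higher and 1017 lower. The count was 1495 without uninjured array 3, 1128 at the threshold of 0.01, 3471 with array weights, 330 with the proximal tubule covariate and 1309 with the macrophage covariate. With the proximal tubule covariate, in which UUO and uninjured arrays do not overlap, 21 of the genes named above for UUO no longer passed. The naming rule gave 104 called genes for this comparison in all, of which 36 passed with the covariate. Among these 21, the changes that shrank most relative to their size were those of Ugt3a2 (log2 -1.30), Slc27a2 (log2 -1.54), Cltrn (log2 -1.94), Acsm2 (log2 -1.80), Cyp2j5 (log2 -0.95), Cyp4a10 (log2 -1.25), Hadhb (log2 -0.72) and Acadvl (log2 -0.20). Slc27a2 is a member of the proximal tubule list, so its shrinking with this covariate is built in. Calb1 (log2 -3.17), Tnc (log2 2.26), P4ha3 (log2 2.90), Inhba (log2 2.25), Skil (log2 1.34), Tgfbi (log2 2.76), Wnt5a (log2 2.49), Frzb (log2 2.95) and Cd74 (log2 0.90) shrank less. Those of Postn (log2 4.94), Rrm2 (log2 2.19), Cenpf (log2 -0.77) and Lyz2 (log2 3.36) were no smaller, so the lost call does not show that the difference went. The calls of Cd74, Mrc1 and Cenpf ended when any 1 of 4, 8 and 5 arrays was left out.

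**Figure D2:**
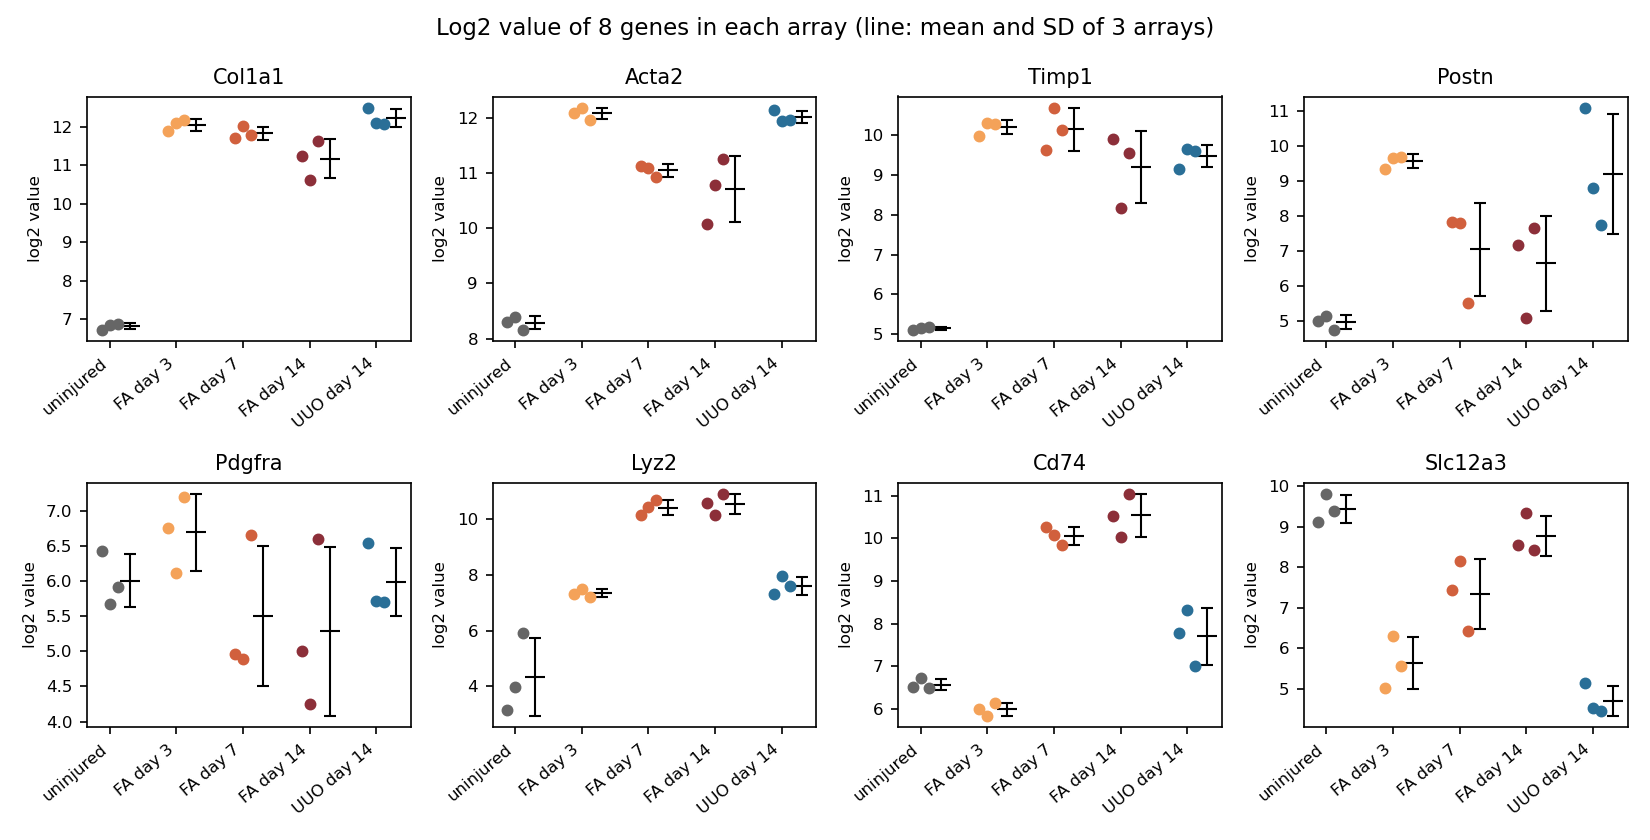
Log2 value (vertical axis) of 8 genes in each of the 15 arrays by group (horizontal axis; FA, folic acid); points are arrays, and the black line with its bar is the mean with the SD of 3 arrays. Col1a1, Acta2 and Timp1 are lowest in the uninjured arrays (Col1a1 mean 6.81, against 11.17 or more in the injury groups), Lyz2 is highest at folic acid day 7 and day 14 (means 10.40 and 10.52), and Slc12a3 is lowest in UUO.

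UUO was set against folic acid day 14 to compare the chronic and the acute model at the same day. Pgr, the progesterone receptor, went from 4.35 ± 0.02 at folic acid day 14 to 7.87 ± 0.73 in UUO (log2 3.53, SE 0.30, adjusted p = 0.000323). Other genes higher in UUO were the matrix gene Hmcn1 (log2 3.41, SE 0.43, adjusted p = 0.00271), Lox (log2 3.21, SE 0.59), the proteoglycan lumican (Lum; log2 3.16, SE 0.67), P4ha3 (log2 2.99, SE 0.47) and Frzb (log2 2.93, SE 0.55). The genes lowest in UUO were the transport protein gene Ttr (log2 -5.67, SE 0.98), the distal tubule calcium-binding gene Calb1 (log2 -5.05, SE 0.61) and Cltrn (log2 -4.92, SE 0.93). Next were Ugt3a2 (log2 -4.83, SE 1.16), the proximal tubule efflux transporter Slc47a1 (log2 -4.70, SE 0.82) and Slc27a2 (log2 -4.67, SE 0.90). Acta2 was 2.48-fold higher in UUO (log2 1.31, SE 0.23, adjusted p = 0.0117). Col1a1 was 2.08-fold higher (log2 1.05, SE 0.22, adjusted p = 0.0254), while Col3a1 (log2 0.94, adjusted p = 0.273), Fn1 (log2 1.11, adjusted p = 0.0991) and Postn (log2 2.56, adjusted p = 0.132) did not pass.

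Collagens were higher in UUO in 10 of 16 cases, 13 adjusted over the list alone, including Col8a2 (log2 1.95), Col6a1 (log2 1.48) and Col6a3 (log2 2.18). The median was 1.30 and the adjusted p was 0.057 with an estimated correlation. Matrix glycoproteins were higher in 7 of 23 cases, 17 adjusted over the list alone, including Vcan (log2 2.32), Mfap4 (log2 2.49) and Thbs2 (log2 2.17). Collagen processing genes were higher in 4 of 14 cases, 7 adjusted over the list alone, and both shifts held with an estimated correlation (adjusted p = 0.043 with an estimated correlation for each). Macrophage markers were lower in UUO in 10 of 21 cases, 19 adjusted over the list alone, with Ctss at log2 -3.76, H2-Ab1 at log2 -3.15 and Cd74 at log2 -2.84 (median -1.78, adjusted p = 0.043 with an estimated correlation). Distal nephron markers were lower in 11 of 15 cases, 14 adjusted over the list alone (median -1.90, adjusted p = 0.043 with an estimated correlation). Proximal tubule markers were lower in 4 of 13 cases, 10 adjusted over the list alone (median -2.71, adjusted p = 0.12 with an estimated correlation). In all 410 genes passed, 173 higher in UUO and 237 lower. The count was 240, 220 and 698 without folic acid day 14 arrays 1, 2 and 3, and 223, 163 and 216 without UUO arrays 1, 2 and 3. It was 266 without uninjured array 2, 79 at the threshold of 0.01, 94 from only the 6 arrays compared, 272 with the macrophage covariate and 15 with the proximal tubule covariate. With the proximal tubule covariate, in which these groups do not overlap, Pgr, Cd74 and Ctss passed of the genes named here and the others did not. Their changes shrank in some cases, as for Ugt3a2 (log2 -0.69), Slc27a2 (log2 -1.12), Slc47a1 (log2 -1.37), Lox (log2 1.46) and Col6a1 (log2 0.60). In others they stayed about as large or grew, as for Vcan (log2 3.14), Mfap4 (log2 2.63), Col8a2 (log2 1.97), Lum (log2 3.02) and H2-Ab1 (log2 -2.96). Slc27a2 is a member of the list behind the covariate, so its shrinking is built in. The calls of Lox, Lum, Frzb, Cltrn, Ugt3a2, Slc27a2 and Col1a1 ended when any 1 of 2, 5, 1, 3, 12, 4 and 5 arrays, in that order, was left out. Those of Slc5a12, Aqp1 and Fbp1 ended without any 1 of 9, 8 and 11 arrays, and all 4 proximal tubule calls ended without UUO array 2. Those of Loxl1 and Loxl2 ended without any 1 of 2 and 4 arrays. Without UUO array 1, P4ha3 alone of the 4 collagen processing genes kept its call.

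**Figure D3:**
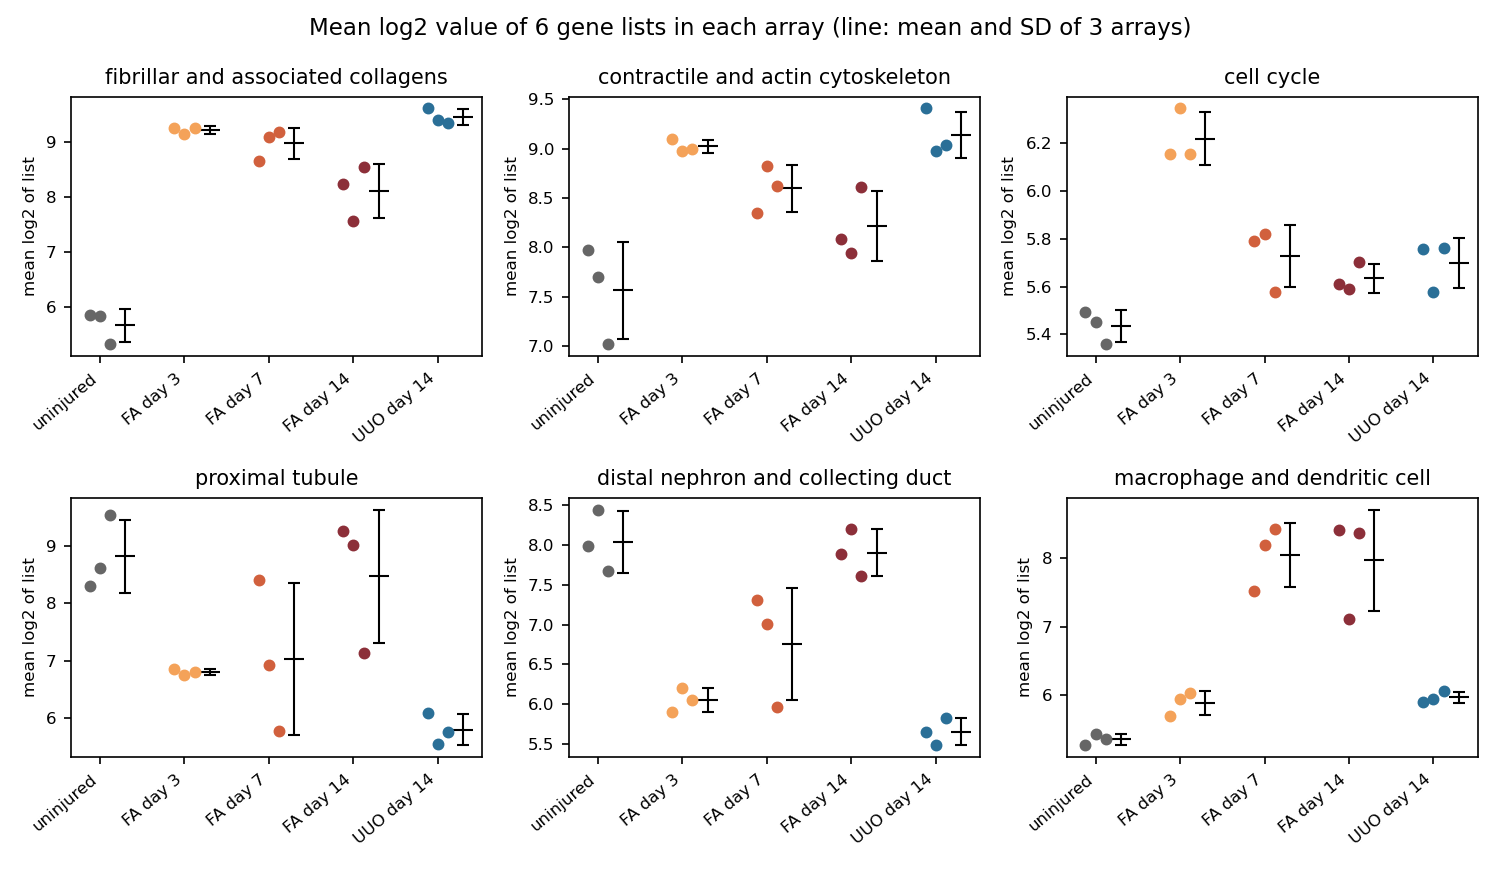
Mean log2 value (vertical axis) over the tested members of 6 gene lists in each of the 15 arrays by group (horizontal axis; FA, folic acid); points are arrays, and the black line with its bar is the mean with the SD of 3 arrays. The collagen mean lies between 5.32 and 5.86 in uninjured arrays and at 7.57 or above in injured ones, and folic acid day 14 arrays 1 and 2 have proximal tubule means of 9.27 and 9.02.

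The time course after folic acid was followed by comparing its days with one another. From day 3 to day 7, Cd74 rose 16.8-fold (log2 4.07, SE 0.30, adjusted p = 4.43e-05), H2-Ab1 rose 15.6-fold (log2 3.96, SE 0.35). The apelin receptor gene Aplnr rose 33.3-fold (log2 5.06, SE 0.88, adjusted p = 0.0230). Lrrn1 (log2 -4.48, SE 0.58), Aldh1a1 (log2 -3.43, SE 0.29) and Adam22 (log2 -2.87, SE 0.40) fell. Macrophage markers rose in 8 of 21 cases, 17 adjusted over the list alone (median log2 2.32, camera adjusted p = 6.9e-29, adjusted p = 0.024 with an estimated correlation). Cell cycle genes fell in 4 of 29 cases, 7 adjusted over the list alone, including Birc5 (log2 -1.54) and Ccnb2 (log2 -1.57) (median -0.55, adjusted p = 0.022 with an estimated correlation). Acta2 was 1.03 lower at day 7 (SE 0.23, adjusted p = 0.0666), and Col1a1, Col3a1, Fn1 and Timp1 did not pass either. In all 94 genes passed, 37 higher and 57 lower. The count was 40, 44 and 50 without day 3 arrays 1, 2 and 3, and 31 and 180 without day 7 arrays 2 and 3. It was 62 without uninjured array 2, 157 without the 3 tubule-rich arrays, 20 at the threshold of 0.01, 16 from only the 6 arrays compared, 171 with the proximal tubule covariate and 11 with the macrophage covariate. The calls of Aplnr, Birc5, Ccnb2, Kif20a and Rrm2 ended when any 1 of 5, 4, 4, 12 and 11 arrays, in that order, was left out. All 4 cell cycle calls ended without day 3 array 2, and also without day 7 array 2.

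From day 7 to day 14 7 genes passed. Epb41l4b, which encodes a membrane skeleton protein, was higher (log2 1.03, SE 0.13, adjusted p = 0.0268). The other 6 were lower, among them Clca3a1 (log2 -3.29, SE 0.47), Itih5 (log2 -2.51, SE 0.27, adjusted p = 0.00735), Gem (log2 -2.33, SE 0.36) and Nkd2 (log2 -1.95). None of 16 collagens passed over all genes and 10 were lower adjusted over the list alone (median -0.88, adjusted p = 0.14 with an estimated correlation). Of 15 distal nephron markers 9 were higher adjusted over the list alone (median 1.18, adjusted p = 0.14 with an estimated correlation). At an unadjusted p under 0.05 there were 1194 genes. The count was 39 and 2 without day 7 arrays 1 and 2, 3 and 50 without day 14 arrays 1 and 3, and 2 and 4 without day 3 arrays 2 and 3. It was 3 and 1 without UUO arrays 1 and 3 and 1 each without uninjured arrays 1 and 2. It was 4 with no filter on dim genes, 28 with the macrophage covariate, 1 at the threshold of 0.01, and 0 with array weights, from only the 6 arrays compared and with the proximal tubule covariate. Of the genes named, only the call of Itih5 held when each array was left out in turn.

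Between day 3 and day 14, Lrrn1 (35.2-fold, log2 -5.14, SE 0.58), Clca3a2 (log2 -4.59, SE 0.68) and Clca3a1 (log2 -4.29, SE 0.47) fell, and Slc22a8 (log2 4.61, SE 1.06), H2-Ab1 (log2 4.59, SE 0.35) and Cd74 (log2 4.55, SE 0.30) rose. Acta2 fell 2.60-fold (log2 -1.38, SE 0.23, adjusted p = 0.00752), and Col1a1 was 0.88 lower on the log2 scale (adjusted p = 0.0546). Collagens fell in 6 of 16 cases, 11 adjusted over the list alone, with Col6a1 at log2 -1.76 and Col14a1 at log2 -2.80 (adjusted p = 0.16 with an estimated correlation). Cell cycle genes fell in 7 of 29 cases, 10 adjusted over the list alone (median -0.45, adjusted p = 0.016 with an estimated correlation). Macrophage markers rose in 9 of 21 cases, 20 adjusted over the list alone (adjusted p = 0.064 with an estimated correlation). Distal nephron markers rose in 7 of 15 cases, 14 adjusted over the list alone (adjusted p = 0.074 with an estimated correlation). Cxcl12, a chemokine of stromal cells, fell by 2.63 on the log2 scale and Aldh1a1 by 3.68. Fos, of the immediate early and dissociation stress list, rose (log2 3.40). In all 412 genes passed, 165 higher and 247 lower. The count was 223, 155 and 199 without day 3 arrays 1, 2 and 3, and 270 without uninjured array 2. It was 110 at the threshold of 0.01, 156 from only the 6 arrays compared, 125 with the proximal tubule covariate and 185 with the macrophage covariate. The call of Slc22a8 ended when any 1 of 9 arrays was left out. With the proximal tubule covariate Acta2 (log2 -1.14, adjusted p = 0.0840) and Cxcl12 (log2 -2.27, adjusted p = 0.0580) no longer passed. Slc22a8 still passed with it but shrank to log2 1.83, while H2-Ab1 (log2 4.47) and Cd74 (log2 4.68) changed little. Slc22a8 is a member of the list behind this covariate, so its shrinking is built in.

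A set of 388 genes was higher and 124 genes were lower in all 4 injury groups compared with uninjured kidney. Independent lists would share 0.41 and 0.040. The count was 0 in 100 simulations of unchanged groups sharing the same controls. Few genes can be called in unchanged groups, so this 0 does not show how many shared calls the controls add. Ranked by the smallest of the 4 rises, the first were Col3a1, Cdh11 and Colec12, which rose by at least log2 5.72, 5.56 and 4.85 in each group. Col15a1 and Aldh1a2 followed (at least log2 4.47 and 4.44). The genes higher in all 4 groups also included many ribosomal protein genes, among them Rplp1, Rplp2, Rps26 and Rps19 (at least log2 2.53, 2.26, 2.17 and 1.97). The cause of their rise was not tested. Folic acid day 14 and UUO shared 436 genes higher and 163 lower, where independent lists would share 51.5 and 15.0. Simulated unchanged groups shared 0, again because few genes can be called in them. Their log2 changes correlated at 0.703 across genes, against 0.512 ± 0.19 (SD) in simulation, and the covariance was 0.382 against 0.0629, a difference of 0.319. With 3 uninjured arrays the controls could not be split between the comparisons, so part of the excess of shared calls over independent lists may come from the shared controls. The simulated covariance already holds their part of the covariance. Only Epb41l4b was called in opposite directions, at log2 0.60 at folic acid day 14 and -0.56 in UUO. The 599 shared calls became 332 without folic acid day 14 array 3 and 387, 293 and 337 without uninjured arrays 1, 2 and 3. They were 916 with array weights, 234 with the proximal tubule covariate and 2 with the macrophage covariate.

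**Figure D4:**
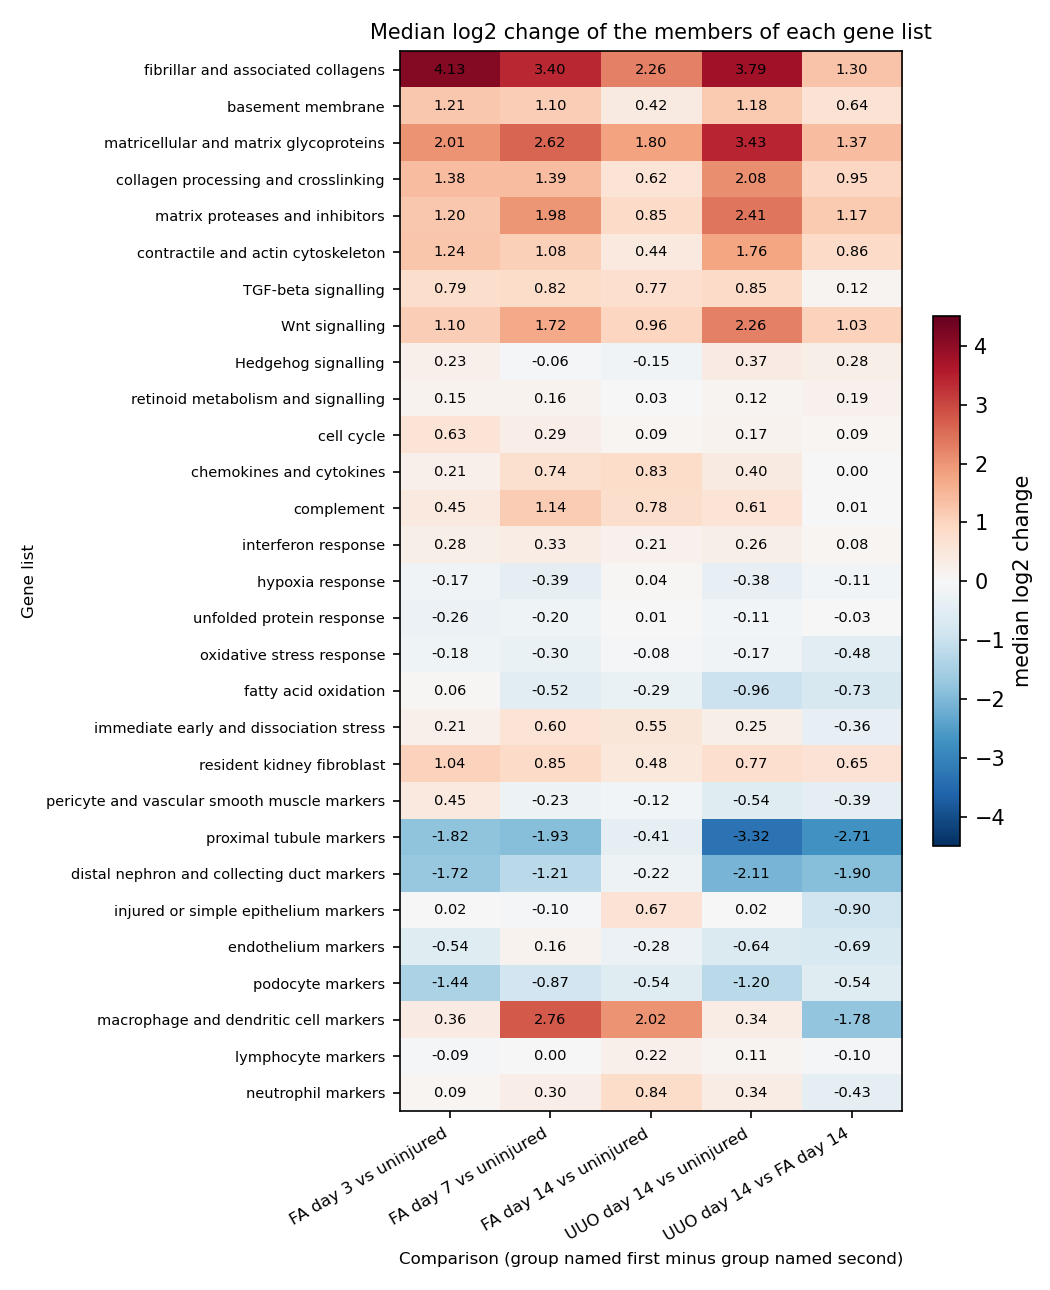
Median log2 change of the tested members of 29 gene lists (rows) in the 5 main comparisons (columns; FA, folic acid); each cell prints the median, and colour runs from blue (lower in the group named first) to red (higher). Collagens have the highest median in folic acid day 3 (4.13) and UUO (3.79) against uninjured kidney, and macrophage markers reach 2.76 and 2.02 at folic acid day 7 and day 14.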

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

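The tests of collagen genes with the proximal tubule mean as a covariate were chosen only after the results were seen. The 2 lists of leukocyte and pan-tubule genes were fixed before their values were looked at.

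Several results differed between injury groups by a direct test. UUO and folic acid day 14 differed in 410 genes, day 7 and day 3 in 94, day 14 and day 7 in 7, and day 14 and day 3 in 412. UUO differed from folic acid day 14 in the medians of matrix glycoproteins (1.37), collagen processing genes (0.95), distal nephron markers (-1.90) and macrophage markers (-1.78). The cell cycle median differed by -0.55 from day 3 to day 7 and by -0.45 from day 3 to day 14. The macrophage median differed by 2.32 from day 3 to day 7. The difference for Epb41l4b between UUO and folic acid day 14 was -1.16 on the log2 scale.

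Probe sets without a gene name, which no comparison used, also differed from uninjured kidney. Of 8559 tested, 1527 passed at folic acid day 3, 1061 at day 7, 659 at day 14 and 1297 in UUO.

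Macrophage genes were higher at folic acid day 7 and day 14, in cells whose sort should remove macrophages. If leukocyte RNA were the source, a second list of 20 tested leukocyte genes should have risen from day 3 to day 7 by a median of at least 1, and if fibroblasts that express antigen presentation genes without leukocytes were the source it should have stayed under 0.5. The median was 0.77 (0.48 to 0.94 with each array left out in turn), 17 of the 20 were higher, and limma called 0 (11 at an unadjusted p under 0.05), while the list as a whole shifted (camera p = 1.0e-08, p = 0.028 with an estimated correlation) and 7 members were called higher at day 7 against uninjured kidney. Of the macrophage markers, H2-Aa had the brightest probe set at day 7 (10.75 ± 0.04), which does not rank RNA abundance between genes. By this second list leukocyte RNA and expression by fibroblasts cannot be told apart, because the value lies between the bounds set for each. The second list was also dim, with means of 5.35 to 5.72 in day 3 arrays, whose medians were 4.93 to 4.98. Since folds against dim values are compressed, the bound of 1 may have been out of reach. The 8 macrophage markers called higher from day 3 to day 7 included C1qb, Fcer1g, Laptm5 and Lyz2, which are not antigen presentation genes. The lower quartile of the change over all 21 markers was 1.12. Of these calls, that of Laptm5 ended when any 1 of 2 arrays was left out. This reading of the marker list was not among the tests set beforehand. By it, the rises over the list argue against fibroblasts that express antigen presentation genes alone as the whole source. Fibroblasts that express further macrophage genes are not addressed by it.

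Tubule genes were lower at folic acid day 3 and in UUO than in uninjured kidney, although the sort should remove tubule cells. A smaller share of tubule RNA should have lowered 20 tested genes of all tubule epithelium by a median of -1 or lower in UUO, and injured tubule cells that lost segment transcripts should have left it above -0.3. The median was -0.44 (-0.60 to -0.41 with each array left out in turn), and of these genes 17 were lower, 1 of them called. The proximal tubule mean was 8.82 ± 0.64 in uninjured kidney and 5.79 ± 0.27 in UUO. The explanations cannot be told apart, because the value lies between their bounds. The pan-tubule list was also dim, with means of 5.76 to 5.86 in uninjured arrays, whose medians were 5.02 to 5.06. Folds against dim values are compressed, so the bound of -1 may have been out of reach.

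Collagen genes were higher in each injury group than in uninjured kidney, and higher in UUO than at folic acid day 14. The collagen median in UUO against uninjured kidney was 3.38 with the proximal tubule covariate and 3.79 without it, and 11 of 16 genes were still called. These groups do not overlap in that covariate (at most 6.09 in UUO, at least 8.31 in uninjured kidney), so the adjusted value is extrapolated and cannot decide. Folic acid day 14 arrays 1 and 2 had proximal tubule means of 9.27 and 9.02, between the lowest (8.31) and highest (9.54) uninjured array, and collagen means of 8.24 and 7.57 against at most 5.86 in uninjured arrays. This match cannot decide on dilution of fibroblast RNA by tubule RNA either. Where most RNA comes from tubules, a log2 tubule mean hardly moves, while the share of fibroblast RNA can still differ severalfold. For UUO against folic acid day 14 the median went from 1.30 to 0.73 and the mean from 1.34 ± 0.24 (SE) to 0.68 ± 0.28 (SE). There limma called 0 of 16 genes with the covariate (7 at an unadjusted p under 0.05), where 10 had been, since the differences shrank and their errors grew, so dilution and a difference between the models cannot be told apart.

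The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. The real split gave 2304 genes for folic acid day 3 against uninjured kidney, 1580 for day 7, 767 for day 14 and 2244 for UUO, and the highest other split gave 0 in each. It gave 410 for UUO against folic acid day 14 (highest other 2), 94 for day 7 against day 3 (highest other 0) and 412 for day 14 against day 3 (highest other 1). For day 14 against day 7 it gave 7, and 3 splits, the real one included, gave as many. The split of day 7 array 1 and day 14 arrays 1 and 2 from the rest gave 221, and since these are the arrays rich in tubule markers this points to a structure of the samples. For gene lists the real and highest other counts were 14 and 11, 18 and 17, 13 and 18, and 18 and 15 for folic acid day 3, day 7, day 14 and UUO against uninjured kidney. They were 17 and 13 for UUO against folic acid day 14, 10 and 7 for day 7 against day 3, 12 and 15 for day 14 against day 7, and 14 and 12 for day 14 against day 3. At folic acid day 14, 4 splits, the real one included, gave as many lists as the real one, and for day 14 against day 7, 2 did. For the F test over the 5 groups, 1 of 100 splits, the real one, gave as many as 2070 genes, and the highest other gave 1837. A random assignment of the arrays is therefore an unlikely source, as far as 100 splits can show. Splits of arrays cannot exclude differences between animals or preparations, since the arrays of a group may come from the same animal. The highest other count depends on the draw: in a second draw of 99 other splits, made after the first was seen, it was 641.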

How the results depend on the processing

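The covariates and the omission of 3 arrays were chosen after seeing the data. Under quantile normalization, median centring, trend and robust settings and the 60th percentile filter, every count of genes and lists for the 8 comparisons and the F test stayed within 1.5 times its value. No called list or named gene reversed under them. The cause was not tested for any change given here, except that a stricter threshold lowers a count by construction. Fewer arrays leave less data, yet some counts rose when an array was left out. Signal over background was not measured, which limits statements on dim genes.

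At a threshold of 0.01 the counts were 1114 for folic acid day 3 against uninjured kidney, 619 for day 7, 263 for day 14, 1128 for UUO, 79 for UUO against folic acid day 14, 20 for day 7 against day 3, 1 for day 14 against day 7 and 110 for day 14 against day 3. From only the 6 arrays compared they were 397 for day 14 against uninjured kidney, 94 for UUO against folic acid day 14, 16 for day 7 against day 3, 0 for day 14 against day 7 and 156 for day 14 against day 3. Array weights gave 3471 genes for UUO against uninjured kidney, 3291 in the F test, 916 calls shared by folic acid day 14 and UUO, and 0 for day 14 against day 7, where no filter on dim genes gave 4. Beside the 0 from array weights, only the 6 arrays and the proximal tubule covariate, limma gave 880, 756 and 1006 genes at an unadjusted p under 0.05. The mean of probe sets reversed Sel1l at folic acid day 14 (0.10).

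With an estimated correlation, 1, 0, 0 and 3 lists shifted at folic acid day 3, day 7, day 14 and in UUO against uninjured kidney, 4 in UUO against folic acid day 14, 2 for day 7 against day 3, 0 for day 14 against day 7 and 1 for day 14 against day 3. With fry, 5 lists shifted for day 7 against day 3 and 5 for day 14 against day 7.

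With the proximal tubule covariate the counts were 1050 for folic acid day 3 against uninjured kidney, 744 for day 7, 330 for UUO, 15 for UUO against folic acid day 14, 171 for day 7 against day 3, 0 for day 14 against day 7, 125 for day 14 against day 3, 973 in the F test and 234 shared calls, and 11 lists shifted in UUO against uninjured kidney. It reversed Cat (0.37) and Slc22a8 (0.21) in UUO against uninjured kidney, groups that do not overlap in this covariate, so these values are extrapolated. Slc22a8 is also a member of the list behind the covariate, which by construction brings its change near 0. The covariate reversed the median of the fatty acid oxidation list in UUO (0.41), in UUO against folic acid day 14 (0.36) and for day 14 against day 7 (-0.13). It reversed that of the proximal tubule list in UUO (0.11) and for day 14 against day 7 (-0.091), which its own construction brings near 0. For fatty acid oxidation at folic acid day 7 (-0.064) and the proximal tubule list in UUO against folic acid day 14 (-0.034) the median shrank without a change of sign, and only the direction of the camera test turned. It reversed the macrophage list in UUO (-0.24) and the oxidative stress list in UUO against folic acid day 14 (0.040).

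With the macrophage covariate, which was 7.11 or above in every folic acid day 7 and day 14 array and 6.06 or below in the others, the counts were 1514, 9, 2 and 1309 for folic acid day 3, day 7, day 14 and UUO against uninjured kidney, 272 for UUO against folic acid day 14, 11 for day 7 against day 3, 28 for day 14 against day 7, 185 for day 14 against day 3 and 2 shared calls. It left 2 lists shifted at day 7 and 6 at day 14, and 33 of 232 list values and 29 of 696 named gene values reversed. Without the 3 tubule-rich arrays the counts were 125 for UUO against folic acid day 14, 157 for day 7 against day 3, 11 for day 14 against day 7 and 202 for day 14 against day 3.

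With each array left out in turn, the counts ranged from 1463 to 2450 for folic acid day 3 against uninjured kidney, 880 to 1751 for day 7, 350 to 892 for day 14, 1495 to 2385 for UUO, 163 to 698 for UUO against folic acid day 14, 31 to 180 for day 7 against day 3, 1 to 50 for day 14 against day 7, 155 to 527 for day 14 against day 3, 1107 to 2290 in the F test and 293 to 649 shared calls. The lists ranged from 12 to 15, 15 to 18, 8 to 15 and 16 to 18 for the 4 injury groups in the same order, 13 to 18, 8 to 13, 9 to 14 and 12 to 16 for the other comparisons. The 8 came without folic acid day 14 array 3.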

Other observations

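Of 17 genes of the resident kidney fibroblast list, 7 rose at folic acid day 3, 4 at day 7, 4 at day 14 and 7 in UUO against uninjured kidney, and 9, 7, 5 and 8 were higher adjusted over the list alone. The transcription factor gene Tcf21 rose by log2 4.52, 4.09, 3.03 and 4.48. In the same order 1, 1, 0 and 2 members fell. Of the 4 calls at day 14, those of Penk and Dpt ended when any 1 of 5 and 11 arrays, in that order, was left out. The list shifted upward by camera in each case (medians 1.04, 0.85, 0.48 and 0.77) and in none with an estimated correlation (adjusted p = 0.061, 0.10, 0.16 and 0.071 with an estimated correlation). Basement membrane genes rose in 7, 8, 1 and 7 of 11 cases, with the laminin gene Lama2 at log2 3.29, 2.47, 1.57 and 2.94. The call of Lama2 at day 14 ended when any 1 of 12 arrays was left out, and in UUO it no longer passed with the proximal tubule covariate (log2 1.29, adjusted p = 0.127). Col4a3 fell at day 3, at day 7 (log2 -1.89) and in UUO (log2 -1.67), and with that covariate stood at log2 -1.40, -1.36 and -0.79 without passing (adjusted p = 0.0895, 0.0956 and 0.548). For the list, adjusted p = 0.17, 0.13, 0.36 and 0.22 with an estimated correlation. The metallothionein gene Mt1 rose by log2 3.45, 2.10, 1.86 and 2.11, while the oxidative stress list it belongs to did not shift against uninjured kidney (camera adjusted p = 0.76, 0.74, 0.65 and 0.17). With the covariate Mt1 stood at log2 1.47 in UUO and did not pass (adjusted p = 0.0532).

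In the order of folic acid day 3, day 7, day 14 and UUO against uninjured kidney, the camera adjusted p was 0.76, 0.97, 0.64 and 0.32 for hedgehog genes, 0.26, 0.049, 0.79 and 0.15 for hypoxia genes, and 0.24, 0.80, 0.68 and 0.91 for the unfolded protein response. It was 0.76, 0.11, 0.45 and 0.40 for interferon genes, 0.76, 0.85, 0.25 and 0.78 for lymphocyte markers and 0.76, 0.20, 0.061 and 0.41 for neutrophil markers. Over these 4 comparisons the medians ran from -0.15 to 0.37 for hedgehog genes, -0.39 to 0.037 for hypoxia, -0.26 to 0.0070 for the unfolded protein response, 0.21 to 0.33 for interferon, -0.086 to 0.22 for lymphocyte and 0.090 to 0.84 for neutrophil genes. The hypoxia shift at day 7 was downward (median -0.39, adjusted p = 0.15 with an estimated correlation). Pericyte markers shifted in UUO alone among the 4 (median -0.54, camera adjusted p = 0.031, adjusted p = 0.22 with an estimated correlation). Endothelial markers also shifted in UUO (median -0.64, camera adjusted p = 0.0034, adjusted p = 0.23 with an estimated correlation). Markers of injured or simple epithelium shifted at folic acid day 14 (median 0.67, camera adjusted p = 0.00068, adjusted p = 0.23 with an estimated correlation), and the injury marker Lcn2 rose by log2 5.51, 4.04, 4.31 and 3.69. With the proximal tubule covariate Lcn2 stood at log2 2.20 in UUO and did not pass (adjusted p = 0.284).

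Between injury groups, some of these lists shifted by camera and none of them with an estimated correlation. In UUO against folic acid day 14 the medians were 0.28 for hedgehog genes (camera adjusted p = 0.0495, 0.12 with an estimated correlation), 0.65 for resident fibroblast genes (0.0495 and 0.14), -0.39 for pericyte markers (0.0495 and 0.18), -0.48 for oxidative stress genes (0.0059 and 0.23), -0.69 for endothelium (0.00021 and 0.14) and -0.90 for injured epithelium (3.0e-05 and 0.12). From day 3 to day 7 they were -0.59 for pericyte markers (0.0027 and 0.13) and 0.58 for endothelium (0.015 and 0.47). From day 7 to day 14 they were -0.59 for basement membrane (0.0085 and 0.23), 0.20 for hypoxia (0.013 and 0.14) and 0.64 for injured epithelium (0.00011 and 0.18). From day 3 to day 14 they were -0.65 for basement membrane (0.026 and 0.25), 0.98 for injured epithelium (7.9e-05 and 0.16) and 0.46 for endothelium (0.021 and 0.35).

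Median, mean and test differed in sign for oxidative stress at day 3 and day 14, injured epithelium at day 3, day 7 and in UUO, and hedgehog genes at day 7. They also differed for the unfolded protein response at day 7, day 14 and in UUO, endothelium at day 7 and day 14, and hypoxia at day 14. In UUO against folic acid day 14 they differed for chemokines, complement and the unfolded protein response, and between folic acid days for matrix proteases, TGF-beta, the unfolded protein response, macrophage markers and oxidative stress.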
